A study of Bos taurus with 16 samples.

How the data were processed

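Bovine blastocysts collected from the uterus at day 7.5 were compared between maternal diets on 16 arrays that each carried 2 samples in the dyes Cy3 and Cy5. Per the labels, the cows were non-lactating Holsteins fed rolled oilseeds for at least 35 days before superovulation: canola (CAN, the control, rich in oleic acid, 8 cows), sunflower (SUN, rich in linoleic acid, 7 cows) or flax (FLX, rich in α-linolenic acid, 8 cows). Embryos of a cow at a similar stage were pooled, and amplified RNA was labelled. Which cows stood behind each replicate was not given in the sources used here. On 8 arrays FLX was set against CAN, and on the other 8 SUN was set against CAN. Each comparison held 4 biological replicates, each hybridised once and once again with the dyes exchanged. FLX lay on slides 1 and 2 and SUN on slides 3 and 4, so slide and diet were nested.

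The deposited values were log2 ratios, 1 per probe and array, as the authors normalised them. The base of the logarithm was assumed to be 2, and the scaling and centring applied by the authors were not given in the sources used here. The direction was taken as Cy5 over Cy3, which is likely from the usual convention and from the placing of the diet samples in Cy5 on the first array of each replicate, with CAN as the control. If the ratio was Cy3 over Cy5, every sign given here turns. The values followed the dyes: all 8 pairs of an array and its dye exchange correlated below 0, from −0.616 to −0.165. Array medians ran from −0.0139 to 0.00947 and SDs over probes from 0.233 to 0.435. No value was missing, no columns were identical, and no samples were left out. Spot intensities were not analysed here, so signal over background is unknown, no filter on weak probes was possible, and the number of arrays limits the precision.

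Each array was turned to diet over CAN, and an array and its dye exchange were averaged, so that a replicate counted once (n = 4 per comparison). Of 43794 probes, 21790 matched 1 gene symbol (15216 genes), 0 matched several and 22004 matched none. Old symbols of 1524 probes were updated, and 21549 probes had their symbol in the gene table of assembly ARS-UCD2.0, used for names and chromosome membership only. Gene-level values were the mean of a gene's probes. R 4.3.3 with limma 3.58.1 and statmod 1.5.0 was used for tests, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for figures.

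One limma model (lmFit and eBayes, 6 residual and 2.32 prior degrees of freedom) over the 8 replicates gave FLX vs CAN, SUN vs CAN and their difference, FLX vs SUN, with two-sided p-values adjusted by Benjamini and Hochberg to a false discovery rate (FDR) of 0.05. A descriptive count took probes at unadjusted p under 0.05 and 1.5-fold. The p-values measure the spread between replicate pools. On data simulated 20 times with 200 changed probes of 43794, the model recovered 85.85% of 2-fold and 97.7% of 4-fold changes in FLX vs CAN, with 13.1 false calls on average, and made 0 calls in the unchanged SUN comparison. A response in both diets was recovered in 81.35% at 2-fold. A list shifted by 0.3 was called in 20 of 20 simulations, with 0.15 other lists called on average. Simulated noise was independent between probes, so these list counts do not show how the list test behaves where genes move together. In the data the estimated inter-gene correlation reached 0.544 for ribosomal protein genes.

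Genes were named by a rule: the 10 highest and 10 lowest per comparison with CAN (5 and 5 for FLX vs SUN) among probes past the FDR threshold with the same sign in 4 of 4 replicates, filled up by the smallest unadjusted p where fewer passed, as values that did not pass. For FLX vs SUN the sign and SD were taken over differences of replicates of the same number. Up to 4 members of smallest p were taken per list. Gene lists were tested by camera with a preset inter-gene correlation of 0.01, by camera with an estimated correlation and by fry, with p-values adjusted over 28 lists. Lists of cell types covered trophectoderm, inner cell mass and epiblast, hypoblast, oocyte and maternal transcripts, cumulus and granulosa cells, blood cells, uterine epithelium and fluid, spermatozoa, Y-linked genes and X-linked sex-dimorphic genes. Metabolic lists covered fatty acid oxidation and ketone bodies, fatty acid synthesis with desaturation and elongation, fatty acid uptake with binding and activation, triglyceride storage and lipid droplets, cholesterol synthesis, PPAR and nuclear lipid receptors, eicosanoid metabolism and receptors, antioxidant and glutathione genes, oxidative phosphorylation, and glycolysis with glucose transport. Further lists covered cell cycle and DNA replication, apoptosis, heat shock and the unfolded protein response, interferon-stimulated genes, DNA methylation and imprinted genes, cytosolic ribosomal proteins, cell junctions and blastocoel formation, and growth factor signalling. Of the measured genes, 22 were in more than 1 list. How many of a list's genes the blastocyst itself expresses could not be counted without intensities. The lists, tests, rule and alternatives were chosen before the data were examined, apart from those chosen after seeing the data: leaving out replicate number 3 of both diets, leaving out a replicate together with an estimated correlation, the test of reversed dyes, the sign counts with each number held out and the tests on XIST and on the causes of the ribosomal shift.

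The CAN samples carried the same numbers in both comparisons, and whether each number was the same RNA pool was not given in the sources used here. Deviations of FLX and SUN replicates from their own group's mean correlated across probes at 0.421, 0.576, 0.537 and 0.410 for numbers 1 to 4, against at most 0.00527 for different numbers. Taking deviations from a group mean itself lowers the values for different numbers. Without it, FLX and SUN replicates correlated at 0.328 to 0.565 for the same number and at most 0.174 for different numbers. The numbers were therefore treated as pairs in differences and averages by number and in the block alternative. The main limma model did not pair them. The CAN samples of a number were assumed to be the same pool wherever FLX minus SUN is said to cancel them. The correlation of the FLX and SUN responses was therefore set beside 1000 simulations without any effect that shared the CAN samples, under the same assumption. Alternatives were centring or scaling each array, all 16 arrays with a dye term, arrays of 1 dye orientation, each comparison on its own 4 replicates, a robust prior, array weights, other probe sets, gene level, slide or replicate number as a block, each replicate left out, other thresholds, an estimated correlation, the most variable probe of a gene and lists without shared genes. Other groupings were counted over the 8 sign changes of 4 replicates and the 35 splits of 8 replicates.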

Results

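Day 7.5 blastocysts were compared between cows on a flax, sunflower or canola diet. The question was whether the kind of oilseed fed to the mother was followed by different transcript levels in her embryos. The 4 replicate pools of each diet, FLX or SUN, were set against a CAN pool on a pair of arrays with exchanged dyes, 16 arrays in all. The arrays measured 43794 probes, of which 21790 carried 1 of 15216 gene symbols. The number of arrays limits the precision, and the median standard error of a probe's mean log2 ratio was 0.0735 for each diet against CAN and 0.104 for FLX vs SUN. Signs are those of diet over CAN with Cy5 over Cy3, the likely direction, and log base 2. With the opposite direction every sign below turns.

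Replicates of 1 diet shared little of their pattern. Over all probes, FLX replicates correlated with each other at −0.264 to 0.0482 and SUN replicates at −0.266 to 0.30, with SUN replicate 3 at −0.244, −0.266 and −0.244 to the others. FLX and SUN replicates of the same number, whose CAN samples carried 1 number and were assumed to be 1 pool, correlated at 0.328, 0.565, 0.471 and 0.412. These correlations are across probes, which are not independent replicates. The sign was the same in all 4 replicates for 10.3% of probes in FLX and 13.7% in SUN, against 12.5% by chance.

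**Figure D1:**
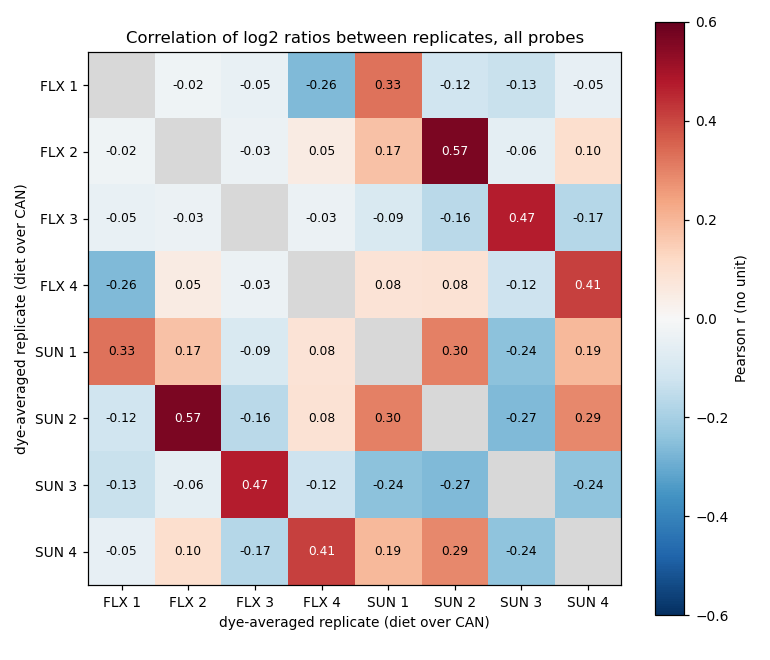
Pearson correlations across 43794 probes between the 8 dye-averaged replicates of diet over CAN. Pairs of the same number (0.328 to 0.565) exceed every pair of the same diet (−0.266 to 0.30).

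The FLX vs CAN comparison set flax seed, rich in α-linolenic acid, against canola seed, rich in oleic acid. Genes of cytosolic ribosomal proteins, the protein part of the translating ribosome, were lower in FLX embryos relative to the other genes: 44 of 62 measured members were negative and 18 positive, with a median log2 ratio of −0.10 (SD of replicate medians 0.26, n = 4). RPS15 stood at −0.37 ± 0.40, RPL29 at −0.34 ± 0.39, RPS29 at −0.28 ± 0.29 and RPL37 at −0.26 ± 0.34 (mean ± SD, n = 4 here and below), and 1 member was under an unadjusted p of 0.05. The shift passed camera at an adjusted p of 0.000197 with the preset correlation, in 3 of 4 replicates. It was lost with adjusted p = 0.963 with an estimated correlation, and fry, which tests the list against no change and not against other genes, gave an adjusted p of 0.971. Leaving out FLX replicate 1, whose median was −0.43, turned the median to 0.019 with an adjusted p of 0.721, and leaving out FLX replicate 4 moved it to −0.20.

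Oxidative phosphorylation genes came next among the FLX lists, with 51 of 75 members negative, a median of −0.054 and an adjusted p of 0.0556 that missed the threshold. The members of smallest p were NDUFA10, a complex I subunit, at −0.19 ± 0.06, SDHA, the flavoprotein of succinate dehydrogenase, at −0.13 ± 0.05, ATP5F1B, the catalytic subunit of ATP synthase, at 0.25 ± 0.20 and NDUFS8, another complex I subunit, at −0.27 ± 0.29. This list passed without FLX replicate 2 (adjusted p = 0.0392) and without FLX replicate 3 (median −0.094, adjusted p = 5.66e-05), but with adjusted p = 0.794 and 0.997 with an estimated correlation. Without FLX replicate 1 its adjusted p was 0.738, and without FLX replicate 4 it was 0.105. Its replicate medians were −0.27, −0.028, 0.093 and −0.043, lowest in FLX replicate 1.

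Single genes with the smallest unadjusted p in FLX, all with the same sign in 4 of 4 replicates, did not pass the threshold (adjusted p = 1.00 in limma). On the positive side were PLA2G5, a secreted phospholipase that frees fatty acids from phospholipids, at 0.41 ± 0.12 (1.33-fold, probe EMBV3_43153), and PDHX, a component of the pyruvate dehydrogenase complex, at 0.50 ± 0.20 (1.42-fold), though its other probe stood at −0.097. HNRNPH3, a splicing factor, stood at 0.64 ± 0.18 (1.56-fold), TEX12 of the synaptonemal complex at 0.48 ± 0.12, KIT, the receptor of stem cell factor, at 0.37 ± 0.06 and the deubiquitinase USP38 at 0.36 ± 0.10. KIT stood at 0.59 with CAN in Cy3 only and 0.15 with CAN in Cy5 only, USP38 at 0.59 and 0.13, NUP133 at 0.35 and 0.082. SLC4A7, a bicarbonate cotransporter, had 0.33 ± 0.16, TMEM209 0.33 ± 0.18, ATIC of purine synthesis 0.30 ± 0.04 and NUP133 of the nuclear pore 0.21 ± 0.04. On the negative side were ENHO, which encodes adropin, at −0.77 ± 0.39 (1.70-fold lower), TCTA at −0.61 ± 0.21 (1.53-fold lower) and ALDH3A2, the fatty aldehyde dehydrogenase, at −0.52 ± 0.16 (1.44-fold lower). MYL6, a non-muscle myosin light chain, stood at −0.42 ± 0.16, and all 10 of its other probes were negative (−0.44 to −0.26). TALDO1, the transaldolase of the pentose phosphate pathway, stood at −0.40 ± 0.14, the small GTPase NRAS at −0.34 ± 0.16, and ABRAXAS2, a scaffold of the BRISC deubiquitinase complex, at −0.33 ± 0.04. CMTM8 had −0.30 ± 0.11 (−0.54 with CAN in Cy3 only, −0.052 with CAN in Cy5 only), U2AF1, which recognises splice acceptor sites, −0.29 ± 0.02, and RASSF9 −0.28 ± 0.06. Other probes had the same sign for 1 of 2 of NRAS, 2 of 3 of ALDH3A2, 3 of 4 of ABRAXAS2 and 4 of 5 of TALDO1, and for all of TEX12 (0.060 to 0.076) and USP38 (0.042 to 0.058).

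Lipid genes gave no list past the threshold in FLX, with adjusted p from 0.212 to 0.944. Cholesterol synthesis had 19 of 24 members negative (median −0.038, adjusted p = 0.212), with GGPS1, which makes geranylgeranyl diphosphate, at −0.17 ± 0.04 and EBP, a sterol isomerase, at −0.28 ± 0.14. Fatty acid synthesis had 17 of 27 negative (median −0.026), with FADS2, the Δ6 desaturase that acts on linoleic and α-linolenic acid, at −0.56 ± 0.40, SREBF1, a regulator of lipogenic genes, at −0.31 ± 0.22, and ACLY, which makes cytosolic acetyl-CoA, at 0.23 ± 0.20. Fatty acid oxidation had 17 of 32 positive (median 0.010), with the peroxisomal oxidase ACOX3 at 0.23 ± 0.14 and ETFDH, which passes electrons to ubiquinone, at 0.24 ± 0.26. Fatty acid uptake had 17 of 28 negative (median −0.028), with the transporter SLC27A4 at −0.24 ± 0.14. Triglyceride storage stood at a median of −0.0082, with ABHD5, the activator of adipose triglyceride lipase, at −0.18 ± 0.13. PPAR and nuclear lipid receptors had a median of 0.0028 with RXRA, the common receptor partner, at 0.11 ± 0.08, and eicosanoid genes −0.0024 with PTGES, a prostaglandin E synthase, at −0.26 ± 0.26.

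Markers of the blastocyst lineages also stayed short of the threshold in FLX. The trophectoderm list had 14 of 23 members negative (median −0.056, adjusted p = 0.436), with CDX2, the trophectoderm transcription factor, at −0.21 ± 0.26. Medians were 0.021 for inner cell mass and epiblast, 0.028 for hypoblast, 0.013 for oocyte and maternal transcripts and 0.046 for X-linked sex-dimorphic genes. Lists for other cells that a flushed sample could hold had medians of −0.035 (cumulus and granulosa), −0.00082 (blood), −0.0023 (uterine epithelium) and −0.0091 (spermatozoa), and the 4 measured of 13 Y-linked genes had 0.036. Adjusted p for these 9 lists other than trophectoderm ran from 0.436 to 0.986. Among the remaining lists the medians were 0.0081 for glycolysis, −0.0062 for antioxidant, 0.00045 for cell cycle, −0.014 for apoptosis, −0.015 for heat shock, −0.0028 for interferon-stimulated, −0.0075 for DNA methylation, −0.014 for cell junction and −0.023 for growth factor genes, with adjusted p from 0.788 to 0.986. Members with the smallest p included PGK1, a glycolytic kinase, at 0.38 ± 0.22, KIF11, the spindle kinesin, at −0.21 ± 0.08, MCM6 of the replicative helicase at 0.23 ± 0.12, the imprinted gene NDN at 0.42 ± 0.26, IRF7, a regulator of interferon genes, at −0.43 ± 0.29, and TSC1, an inhibitor of mTOR signalling, at 0.14 ± 0.04.

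Over the whole array, limma called 0 probes in FLX at an FDR of 0.05, while 1273 had an unadjusted p under 0.05 (694 positive, 579 negative) against 2190 expected by chance, and 35 of them (12 positive, 23 negative) reached 1.5-fold. Leaving out FLX replicate 1, 3 or 4 moved the last count to 104, 76 or 136. Of the list members, 26 had an unadjusted p under 0.05, 0 passed over all genes and 0 passed adjusted over the list alone. Median, mean and test differed in sign for 9 lists, namely inner cell mass, hypoblast, blood, uterine epithelium, spermatozoa, Y-linked, PPAR, interferon-stimulated and DNA methylation genes.

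**Figure D2:**
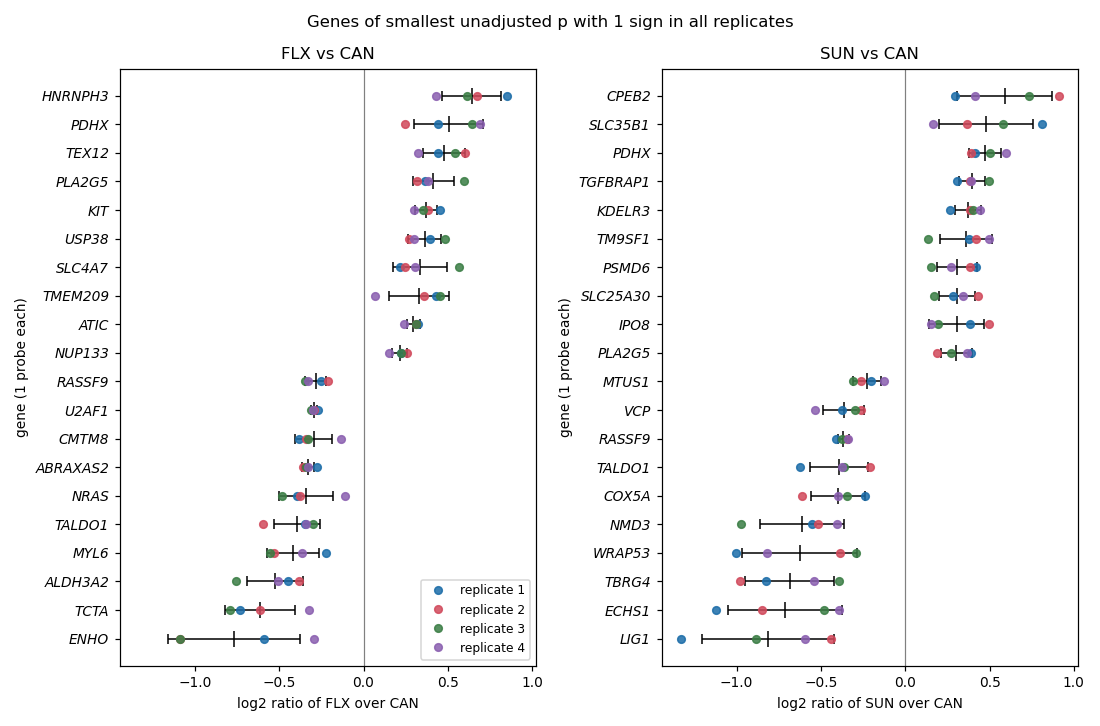
Log2 ratios over CAN of the named genes in FLX and SUN, with a point per replicate (n = 4) and the mean with its SD. LIG1 in SUN (−0.81 ± 0.39) and ENHO in FLX (−0.77 ± 0.39) lie lowest among these genes.

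The SUN vs CAN comparison set sunflower seed, rich in linoleic acid, against canola seed, rich in oleic acid. Among the genes named for their smallest unadjusted p in SUN embryos, the lowest were LIG1, the DNA ligase that joins replicated strands, at −0.81 ± 0.39 (1.76-fold lower), ECHS1, the enoyl-CoA hydratase of mitochondrial β-oxidation, at −0.71 ± 0.34 (1.64-fold lower) and TBRG4, a mitochondrial RNA regulator, at −0.69 ± 0.27 (1.61-fold lower). The highest of these named genes were CPEB2, which binds cytoplasmic polyadenylation elements, at 0.59 ± 0.28 (1.5-fold), SLC35B1, a nucleotide transporter of the endoplasmic reticulum, at 0.48 ± 0.28, and PDHX at 0.48 ± 0.10, whose other probe stood at −0.039. Each had its sign in 4 of 4 replicates, and none passed limma (adjusted p = 0.583 for TBRG4 and RASSF9, 0.774 for the others). Further negative values were WRAP53, a factor of telomerase trafficking, at −0.63 ± 0.34, NMD3, an export adaptor of the large ribosomal subunit, at −0.61 ± 0.25, COX5A of cytochrome c oxidase at −0.40 ± 0.16, TALDO1 at −0.39 ± 0.17, RASSF9 at −0.37 ± 0.03 (−0.014 with CAN in Cy3 only and −0.72 with CAN in Cy5 only), the ATPase VCP, which extracts ubiquitinated proteins, at −0.37 ± 0.12 (its other probe at 0.082, and −0.69 and −0.044 with CAN in Cy3 only and in Cy5 only) and MTUS1 at −0.23 ± 0.08. Further positive values were TGFBRAP1 at 0.40 ± 0.08, KDELR3, a receptor that returns proteins to the endoplasmic reticulum, at 0.37 ± 0.08, TM9SF1 at 0.36 ± 0.16, PSMD6 of the proteasome at 0.31 ± 0.12, the mitochondrial carrier SLC25A30 at 0.31 ± 0.11, PLA2G5 at 0.30 ± 0.09 and the importin IPO8 at 0.30 ± 0.16. Other probes had the same sign for 1 of 3 of NMD3 (−0.097 to 0.18), 1 of 3 of COX5A (−0.021 to 0.088), 1 of 2 of TGFBRAP1 and 4 of 5 of TALDO1.

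No list passed in SUN, and the lowest adjusted p, 0.136, was that of cholesterol synthesis and of cumulus and granulosa genes. Cholesterol synthesis had 19 of 24 members positive and a median of 0.15, with replicate medians of 0.23, 0.41, −0.15 and 0.083 and with 5 members under an unadjusted p of 0.05. Examples were NSDHL, a sterol dehydrogenase, at 0.30 ± 0.22, IDI1, the isopentenyl diphosphate isomerase, at 0.66 ± 0.82, and SCAP, the escort protein of SREBP, at −0.26 ± 0.16. Trophectoderm genes had 17 of 23 positive and a median of 0.13 (replicates 0.10, 0.44, −0.28 and 0.093), with PAG2, a pregnancy-associated glycoprotein, at 0.85 ± 0.63 and HAND1, a trophoblast transcription factor, at −0.14 ± 0.17. Cumulus and granulosa genes had 13 of 16 positive (median 0.061), with FSHR, the follicle-stimulating hormone receptor, at 0.22 ± 0.17. Without SUN replicate 3, cholesterol synthesis (median 0.21, adjusted p = 1.29e-05), trophectoderm (0.19, 0.0104), cumulus and granulosa (0.12, 0.0216), fatty acid synthesis (0.066, 0.0228) and oxidative phosphorylation (−0.14, 0.000734) passed with the preset correlation, 5 lists in all. With an estimated correlation and without SUN replicate 3 none passed, with adjusted p = 0.559 for the first 4 and 0.637 for oxidative phosphorylation.

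Other lipid lists in SUN had adjusted p from 0.415 to 0.881. Fatty acid oxidation had 20 of 32 members negative (median −0.024), while HSD17B4 of peroxisomal β-oxidation stood at 0.42 ± 0.52. ECHS1 passed adjusted over the list alone (adjusted p = 0.00586, and 0.00485 to 0.0423 with a replicate left out). That adjustment was made within each list and not across lists or comparisons, so a pass in some list can arise by chance. Leaving out replicates does not correct for this. Over all probes the adjusted p of ECHS1 in limma was 0.774. Fatty acid synthesis had 19 of 27 positive (median 0.056), with the elongase ELOVL4 at 0.22 ± 0.31. Uptake genes had a median of −0.014 with SLC27A4 at −0.20 ± 0.20, triglyceride storage 0.026 with DGAT1, which completes triglyceride synthesis, at 0.18 ± 0.10, PPAR and nuclear lipid receptors 0.023, and eicosanoid genes 0.0065 with PLA2G6, a calcium-independent phospholipase, at −0.37 ± 0.24. Of the cell type lists, medians were 0.0057 for inner cell mass, 0.012 for hypoblast, −0.0049 for oocyte, 0.012 for blood, −0.044 for uterine epithelium (12 of 15 negative), −0.032 for spermatozoa, 0.031 for Y-linked and 0.10 for X-linked dimorphic genes, with adjusted p from 0.533 to 0.976. Heat shock genes had 22 of 35 positive (median 0.044, adjusted p = 0.316) and 6 members under an unadjusted p of 0.05, among them the chaperones PDIA6 at 0.60 ± 0.58, CALR at 0.54 ± 0.53 and HSP90AA1 at 0.52 ± 0.50. Ribosomal protein genes had 32 of 62 positive (median 0.0038, adjusted p = 0.80), with RPS14 at −0.87 ± 0.59 and RPL6 at 0.36 ± 0.22. Oxidative phosphorylation had a median of −0.013 with COX8A at 0.46 ± 0.30, and cell cycle genes −0.013 with MCM5 of the replicative helicase at −0.52 ± 0.40 and the clamp PCNA at 0.30 ± 0.23. Medians elsewhere were 0.075 for glycolysis, −0.010 for antioxidant genes with the peroxidase PRDX2 at 0.30 ± 0.06, −0.029 for apoptosis, 0.023 for interferon-stimulated genes with RSAD2 at 0.21 ± 0.15, 0.031 for DNA methylation with the dioxygenase TET2 at 0.23 ± 0.15, 0.0075 for cell junctions with the tight junction gene OCLN at 0.42 ± 0.24, and 0.0057 for growth factor signalling, with adjusted p from 0.316 to 0.976.

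Over the whole array, limma called 0 probes in SUN, with 2827 at an unadjusted p under 0.05 (1561 positive, 1266 negative) against 2190 expected, and 86 of them (41 positive, 45 negative) reached 1.5-fold. Without SUN replicate 3 these counts were 2 past the FDR, 4657 and 652, the 2 probes having no gene name and log2 ratios of −0.83 and 1.35. Without SUN replicate 2 the last 2 counts were 1835 and 49, and without SUN replicate 4 the 1.5-fold count was 147. Camera with an estimated correlation (lowest adjusted p = 0.836) and fry (0.818) called 0 lists. Of the list members, 59 had an unadjusted p under 0.05 and 0 passed over all genes. Adjusted over the list alone, and not across lists, 1 passed, ECHS1. Median, mean and test differed in sign for 7 lists, namely inner cell mass, oocyte, spermatozoa, Y-linked, antioxidant, ribosomal and growth factor genes.

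The FLX vs SUN comparison tested whether the diets' ratios over CAN differed. Cholesterol synthesis genes were lower in FLX than in SUN relative to other genes, with 20 of 24 members negative and a median difference of −0.14 (SD over numbers 0.16, n = 4; replicate numbers −0.35, −0.27, 0.016 and −0.13; adjusted p = 0.756 with an estimated correlation). EBP had −0.52 ± 0.26, SC5D, a sterol desaturase, −0.31 ± 0.25, and SQLE, the squalene epoxidase, −0.72 ± 1.02. Trophectoderm genes were lower too, with 17 of 23 negative and a median of −0.18 (replicate numbers −0.11, −0.51, 0.083 and −0.093; adjusted p = 0.756 with an estimated correlation), among them PAG2 at −1.20 ± 1.10, ID2, an inhibitor of differentiation, at −0.89 ± 0.66 and the keratin KRT8 at −0.39 ± 0.39. Cumulus and granulosa genes had 12 of 16 negative (median −0.11; adjusted p = 0.756 with an estimated correlation), with the steroidogenic genes HSD3B1 at −1.43 ± 0.96 and STAR at −0.52 ± 0.63. The median of the cumulus list had the same sign in 4 of 4 numbers, as in triglyceride storage and eicosanoid genes, which did not pass. Ribosomal protein genes had 46 of 62 negative (median −0.084, in 3 of 4 numbers; adjusted p = 0.875 with an estimated correlation), with RPL36 at −0.42 ± 0.39 and RPS28 at −0.34 ± 0.37.

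**Figure D3:**
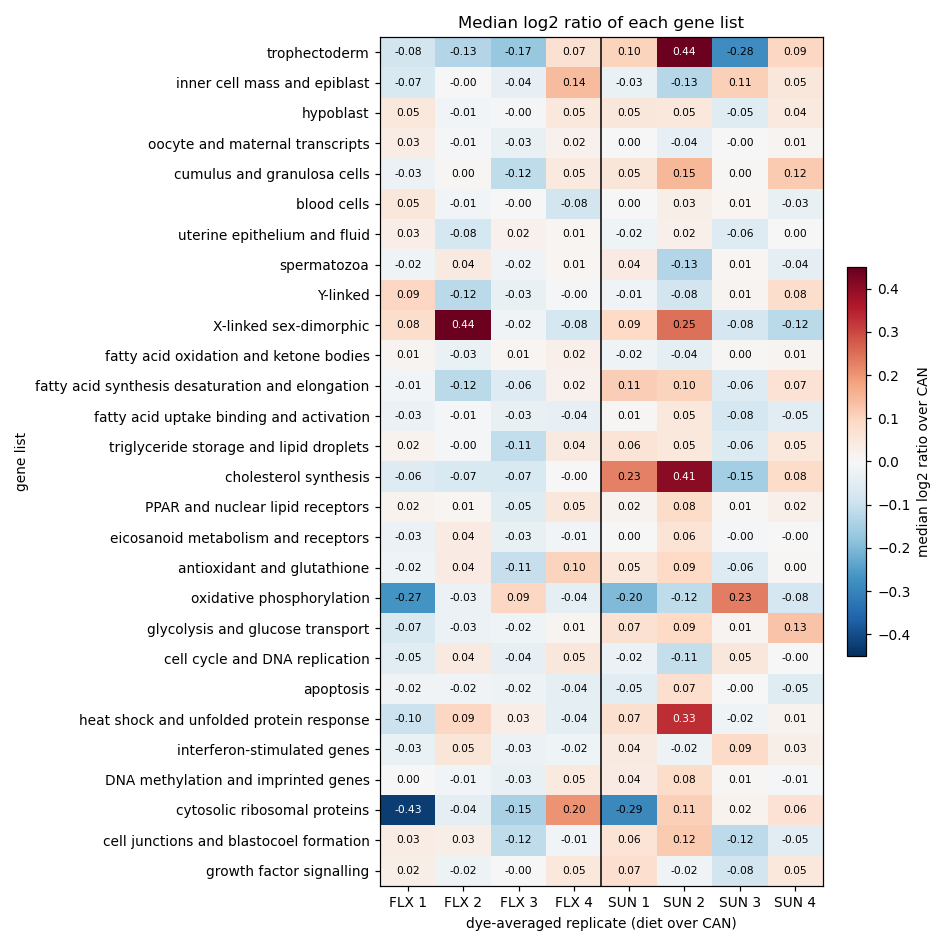
Median log2 ratios over CAN of the 28 gene lists. Values are given per replicate of FLX and SUN (n = 4). Cholesterol synthesis runs from −0.070 to −0.0025 in FLX. In SUN it runs from −0.15 to 0.41.

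These 4 lists passed camera with the preset correlation, at adjusted p of 0.00123 (cholesterol synthesis), 0.0217 (cumulus and granulosa) and 0.0391 (trophectoderm and ribosomal proteins). None passed with an estimated correlation, and fry, against no change, called 0 lists (lowest adjusted p = 0.921). Cholesterol synthesis was lost without SUN replicate 1 (adjusted p = 0.0643) or 2 (0.0803), and its median was −0.30 with the most variable probe of each gene. The cumulus list was lost without FLX replicate 1 (0.0552) or 3 (0.125) or SUN replicate 2 (0.141) or 4 (0.10). Trophectoderm was lost without FLX replicate 1 (0.0630), 2 (0.233) or 3 (0.0760, median −0.12) or SUN replicate 1 (0.182), 2 (0.666, median −0.026) or 4 (0.125), with arrays scaled to an equal spread (0.0587) and with the most variable probe of each gene (0.0688), while its median was −0.34 without SUN replicate 3 and −0.27 without number 3 of both diets. For ribosomal proteins the median turned to 0.031 without FLX replicate 1 (0.613), and the call was lost without FLX replicate 3 (0.145) or SUN replicate 2 (0.740), 3 (0.188) or 4 (0.298), without number 3 of both diets (0.467) and with the most variable probe (0.0688), while the median was −0.24 without FLX replicate 4 and −0.15 without SUN replicate 1. The number of lists called ran from 0 without SUN replicate 2 to 7 without SUN replicate 3 (lowest adjusted p = 0.307 with an estimated correlation), with 1 without FLX replicate 1 or SUN replicate 4.

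Fatty acid synthesis came closest among the other 24 lists, with 20 of 27 members negative (median −0.10, adjusted p = 0.0579; adjusted p = 0.756 with an estimated correlation), FADS2 at −0.87 ± 0.64 and the elongase ELOVL1 at −0.80 ± 0.66. It passed without FLX replicate 4 (adjusted p = 0.0250, and 0.708 with an estimated correlation), without SUN replicate 3 (0.00313, and 0.307), without number 3 of both diets (0.00381) and with 16 arrays and a dye term (0.0167). The remaining medians ran from −0.093 to 0.055, with adjusted p from 0.144 to 0.954. They included −0.093 for heat shock, −0.090 for glycolysis, where the glucose transporter SLC2A1 had −0.43 ± 0.20, −0.039 for triglyceride storage, where ABHD5 had −0.31 ± 0.14, and 0.036 for cell cycle genes, where CDK6 had 0.27 ± 0.12. With the preset correlation oxidative phosphorylation passed without FLX replicate 3 (adjusted p = 0.00539) or SUN replicate 1 (0.00887), and glycolysis without FLX replicate 4 (0.0308). Heat shock passed with 16 arrays (0.0167) and without FLX replicate 3 (0.0364), SUN replicate 3 (0.0392) or number 3 (0.00591). Triglyceride storage and cell cycle genes passed without SUN replicate 3 (0.0392), cell cycle genes also without number 3 (0.0435). None passed with an estimated correlation and a replicate left out. Median, mean and test differed in sign for 5 lists, namely inner cell mass, hypoblast, Y-linked, X-linked dimorphic and fatty acid uptake genes. Single genes with the smallest p were TEX12 at 0.76 ± 0.33 (1.70-fold), KIT at 0.56 ± 0.14 (1.48-fold), C7H1orf35 at 0.43 ± 0.05 (0 of 2 other probes with its sign), PSMC1 of the proteasome at 0.39 ± 0.21 and PHACTR4 at 0.26 ± 0.05. Negative values of smallest p were KDELR3 at −0.61 ± 0.26 (1.52-fold lower), CDC42SE2 at −0.52 ± 0.20 (3 of 3 other probes with its sign), CMTM8 at −0.46 ± 0.04, ABRAXAS2 at −0.41 ± 0.16 and CLDN6, a tight junction claudin, at −0.34 ± 0.04. Other probes had the same sign for 1 of 4 of ABRAXAS2 (−0.13 to 0.13), 1 of 2 of TEX12 (−0.097 to 0.017) and 1 of 2 of PHACTR4 (−0.11 to 0.048). CLDN6 stood at −0.15 ± 0.05 in FLX and 0.19 ± 0.06 in SUN, and turned to 0.052 in FLX vs SUN on the arrays with CAN in Cy5 alone.

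Limma called 0 probes in FLX vs SUN, with 949 at an unadjusted p under 0.05 (431 positive, 518 negative) against 2190 expected, and 2075 without SUN replicate 3. With replicate number as a block, which pairs the diets, 2326 were at an unadjusted p under 0.05 and 0 passed (smallest adjusted p = 0.885). The named genes had an adjusted p of 1.00. Of the list members, 13 had an unadjusted p under 0.05 and 0 passed over all genes. Adjusted over the list alone, and not across lists, 1 passed, CLDN6 (adjusted p = 0.0187). That call was lost without FLX replicate 1 (adjusted p = 0.0501), 2 (0.0833) or 4 (0.0811) and without SUN replicate 1 (0.0640), 2 (0.0516) or 3 (0.0616).

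The last comparison asked whether FLX and SUN moved the same genes away from CAN. RASSF9 (−0.28 in FLX, −0.37 in SUN), TALDO1 (−0.40, −0.39), PDHX (0.50, 0.48) and PLA2G5 (0.41, 0.30) were named in both. Mean log2 ratios of FLX and SUN correlated across 15216 genes at r = 0.312 (Spearman 0.247), where genes are not independent replicates. Sharing the CAN samples alone, if those of a number were the same pool, gave a median r of 0.536 (0.384 to 0.589) in simulations without any effect, so the measured value lay below that range. The covariance was 0.00481, against 0.00898 from the shared CAN samples, and lay inside the simulated range without any effect (0.000603 to 0.0311). With the CAN samples divided between the diets, r ran from −0.263 to 0.0775 over 6 divisions and was below 0 in 5. Probes at an unadjusted p under 0.05 in both diets numbered 156 positive and 155 negative, against 24.7 and 16.7 for independent comparisons, which these were not.

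XIST, the RNA that silences an X chromosome in female cells, was singled out after its values were seen, with 1 probe on the array. It stood at 0.99, 2.69, −0.91 and −1.89 in FLX replicates 1 to 4 and at 0.93, 2.15, −0.19 and −0.56 in SUN replicates 1 to 4. The median of the 567 measured X-linked genes had the sign of XIST in 8 of 8 replicates and lay between −0.045 and 0.055. The 8 are not independent, since FLX and SUN of a number were assumed to share a CAN pool and had the same sign of XIST. DDX3Y, a Y-linked RNA helicase, ran from −0.63 to 0.015, lowest in FLX replicate 2, then SUN replicate 2 (−0.36), where XIST was highest, then SUN replicate 4 (−0.25), where XIST was negative.

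**Figure D4:**
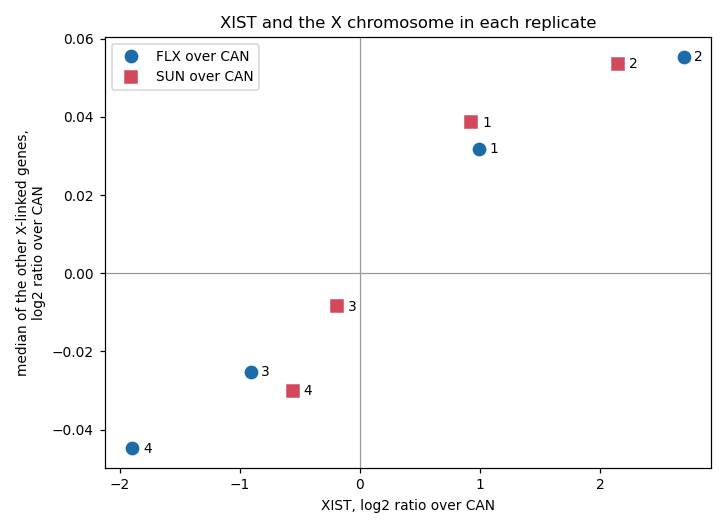
XIST log2 ratio over CAN against the median log2 ratio of 567 X-linked genes, with a point per replicate. The X-linked median has the sign of XIST in 8 of 8 replicates.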

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

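In this part, the test of reversed dyes on the SUN replicate 3 arrays, the comparison of number 3 with the other numbers held out and both tests on ribosomal protein genes were chosen only after the result was seen.

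Replicates far from the other 3 of their group turned up in 4 of 56 groups of list medians and 2 of 50 groups of named-gene values, where chance gives about 1 in 20, or 2.8 and 2.5. The interferon-stimulated list in FLX had a median of 0.053 in replicate 2 against −0.030 to −0.020 in the others. The hypoblast list in SUN had −0.054 in replicate 3 against 0.043 to 0.053. Triglyceride storage in SUN had −0.061 in replicate 3 against 0.047 to 0.063. Eicosanoid genes in SUN had 0.060 in replicate 2 against −0.0038 to 0.00062. TALDO1 in FLX stood at −0.60 in replicate 2 against −0.35 to −0.30. PHACTR4 in FLX vs SUN stood at 0.19 for number 2 against 0.28 to 0.29.

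The diets differed from each other, by the test of FLX vs SUN in camera with a preset correlation, for trophectoderm (adjusted p = 0.0391), cumulus and granulosa (0.0217), cholesterol synthesis (0.00123) and cytosolic ribosomal protein genes (0.0391). With an estimated correlation the adjusted p was 0.756, 0.756, 0.756 and 0.875. The 4 lists called compare with as many or more in 11 of the 35 splits of the 8 replicates and with 9 in the highest other split, so chance cannot be excluded. Among the 8 splits that, like the real one, part all 4 pairs of the same number, 4 gave as many lists, the highest other gave 4, and 536 to 1245 probes were at an unadjusted p under 0.05. The 27 other splits kept pairs together and gave 1452 to 4518 such probes, up to 10 past the FDR against 0 in the real split, which points to a structure of the samples by number. The split that set numbers 1 and 2 against 3 and 4, the order of the slides within each diet, gave 5 lists, and the real split with replicate number as a block gave 4.

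SUN replicate 3 ran against the other SUN replicates: of 1144 probes with an unadjusted p under 0.01 over SUN replicates 1, 2 and 4 alone, 22.4% had the sign of their mean in it, where chance gives 50% and the same selection with another number held out gave 59.2% to 63.1%. Reversed dyes on its arrays alone are argued against, because its deviation from the SUN mean correlated with that of FLX replicate 3 at 0.537. Dyes exchanged on its arrays only would turn the shared CAN part to a negative value. A reversal of number 3 in both diets would leave that correlation positive and was not tested. SUN sample 3 may differ from the other SUN samples, since the sign was found in 35.9% for SUN replicate 3 minus FLX replicate 3, where CAN sample 3 cancels if it was the same pool on both sets of arrays, against 54.4% to 70.2% for the other numbers held out. CAN sample 3 stays open: the share in FLX replicate 3 was 35.9%, which met the limit set for this cause before the data were examined. It was not clearly below the 40.8%, 41.3% and 62.1% found for the other numbers held out, a condition added afterwards. The shares of the other numbers rest on 206 to 304 probes, against 1144 for number 3, and SUN replicate 3 took part in choosing them. Neither test tells a technical from a biological difference between the pools, which was not tested.

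Ribosomal protein genes were lower in FLX, mostly through replicate 1, with 59 of 62 members negative there and list medians of −0.43, −0.045, −0.15 and 0.20 in replicates 1 to 4. CAN sample 1 stays open as a cause, since SUN replicate 1 was low as well at −0.29, and the list median of FLX minus SUN, where the CAN sample cancels if it was the same pool, was −0.13, −0.16, −0.15 and 0.13 for numbers 1 to 4, so that the −0.13 of number 1 did not exceed the SD of 0.139 over numbers. Genes of the list moving together within a replicate may account for the call, since the adjusted p was 0.963 with an estimated correlation (0.544). A response to flax in part of the pools stays open, as untested beyond the 4 replicates.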

How the results depend on the processing

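Leaving out replicate number 3 of both diets, and leaving out a replicate together with an estimated correlation (0 lists in each comparison), were chosen only after the result was seen. The 0 probes past the FDR in each comparison stayed 0 at an FDR of 0.10 and under the alternatives other than these: 1 in SUN with 16 arrays and a dye term (TBRG4, −0.69), 1 in FLX and 2 in SUN with CAN in Cy5 only, 0 to 2 in SUN with a replicate left out, and 1273, 2827 and 949 (FLX, SUN, FLX vs SUN) at an unadjusted p under 0.05. The 35 probes at 1.5-fold in FLX became 78 with scale normalisation, 69 with 16 arrays, 359 with CAN in Cy3 only, 122 with CAN in Cy5 only, 20 with named probes only, 9 at gene level, 85 without number 3, 4 at 2-fold, 240 at p under 0.01 with no fold limit, and 45 to 136 with a replicate left out. The 86 in SUN became 43, 166, 334, 478, 50, 26, 675, 7 and 543 under the same settings (543 with no fold limit), and 49 to 652 with a replicate left out. The 1 FLX list became 2 with 16 arrays, 2 with its own 4 replicates, 2 without number 3, 0 with an estimated correlation, and 0 to 2 with a replicate left out. The 0 SUN lists became 1 with 16 arrays, 1 with the most variable probe, 5 without number 3 and 0 to 5 with a replicate left out. The 4 FLX vs SUN lists became 6 with 16 arrays, 6 without number 3, where ribosomal proteins were lost, 3 with scale normalisation, 0 with an estimated correlation, 2 with the most variable probe and 0 to 7 with a replicate left out. Ribosomal medians ran from −0.20 to 0.019 in FLX and −0.24 to 0.031 in FLX vs SUN with a replicate left out, reversing without FLX replicate 1. The correlation of 0.312 became 0.247 by Spearman and ran from 0.307 to 0.421 with a number left out. It reversed to −0.13 with the CAN samples divided, where no CAN number is shared and each mean rests on fewer replicates. CLDN6 in FLX vs SUN reversed to 0.052 with CAN in Cy5 only. Of 680 values of named genes under alternatives, 678 kept their direction and side of the threshold, 1 passed and 1 reversed, but sizes moved by over 1.5 times for 12 of 50 with CAN in Cy3 only and 17 of 50 with CAN in Cy5 only (RASSF9 in SUN −0.014 and −0.72). These genes were chosen here for 1 sign in 4 of 4 replicates or numbers, and none passed in the main model. Keeping direction and side was therefore largely fixed in advance and says little about stability. Of 82 values of called lists, 55 kept both, 25 no longer passed and 2 reversed. Fewer probes or replicates entered with named probes, gene level and left-out replicates. In the model of 16 arrays, 6489 probes had a dye effect past the FDR of 0.05. Arrays of 1 dye orientation do not average such an effect out. How far it accounts for the shifts with CAN in Cy3 only or in Cy5 only was not tested. Elsewhere the cause was not tested. The filter on missing values removed 0 probes. Signal over background, which limits weak probes, is unknown.

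With replicate number as a block, which pairs the diets, 0 probes passed in each comparison, the lists called were 1, 0 and 4 for FLX, SUN and FLX vs SUN, and probes at 1.5-fold were 44 and 95 for FLX and SUN. Probes at an unadjusted p under 0.05 in FLX vs SUN moved from 949 to 2326, against 2190 expected, with a smallest adjusted p of 0.885. The same 4 lists passed, at adjusted p of 0.00103 to 0.00462 with the preset correlation and 0.782 to 0.797 with an estimated correlation.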

Other observations

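Both tests on XIST were chosen only after the result was seen, and the genes of the next paragraph were singled out after their values were seen. The test of a shared response and the counts over other groupings were chosen before the data were examined.

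The genes that differed most between replicate pools, whatever the diet, included lineage genes of the blastocyst. NANOG, a transcription factor of the epiblast, had the second largest SD within diets of the 15216 genes (2.42, against a median of 0.154), with log2 ratios over CAN of −2.19, 2.63, −1.11 and 1.82 in FLX and 0.35, 5.34, −0.30 and 1.51 in SUN replicates 1 to 4. KRT19, a keratin of trophectoderm, followed with an SD of 2.16 and ran from −2.46 in SUN replicate 3 to 3.95 in SUN replicate 2. TKDP1, a trophoblast Kunitz domain protein, ran from −2.95 in SUN replicate 3 to 2.59 in SUN replicate 2. IFNT, the interferon by which the ruminant embryo signals pregnancy, ran from −1.98 in SUN replicate 4 to 1.99 in SUN replicate 2. Of the 40 most variable genes, 4 were among the 23 trophectoderm genes and 1 among the 19 inner cell mass genes. LTF, which encodes lactoferrin, and BPIFB1 had low ratios over CAN in replicate number 3 of both diets. These were −2.21 in FLX and −2.68 in SUN for LTF, and −1.93 and −2.38 for BPIFB1. In the other replicates LTF ran from −0.26 to 0.25 and BPIFB1 from −0.044 to 0.37. Both ratios of number 3 were taken over CAN sample 3, assumed to be 1 pool. High levels in that sample were not told apart from low levels in both diets.

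Gene lists differed in how much their genes varied between replicates. The median gene's SD within diets lay at the 88.5th percentile of all genes for heat shock and unfolded protein response, the 81.9th for hypoblast, the 80.3rd for trophectoderm and the 79.5th for ribosomal protein genes. It lay at the 20.2nd percentile for oocyte and maternal transcripts, the 24.7th for blood cells, the 34.3rd for spermatozoa and the 42.2nd for uterine epithelium. Spot intensities were not analysed, so whether a low spread comes from weak signal is unknown.

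XIST differed between replicates, from −1.89 to 2.69. A different share of female embryos in the pools is a candidate explanation, since the X chromosome had rank 1 of 30 by the median correlation of its genes with XIST over the 8 replicates, 0.236 over 567 genes, against −0.0693 to 0.0937 for the autosomes. The pools' developmental stage stays open, because the trophectoderm median had the sign of XIST in 4 of 8 replicates and none of the 4 opposite medians lay more than 2 standard errors from 0. The CAN pools' share of females enters with the same number in both diets and was not separated. No difference between diets in the sex of embryos was tested.

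A response shared by both diets was tested on the mean of the FLX and SUN ratios by number (n = 4). Limma called 0 probes, and 1627 were at an unadjusted p under 0.05, 3.72% where chance gives 5%, with 886 positive and 741 negative. A shared response of at least 2-fold in 200 probes spread at random over the array is argued against, since such changes were recovered in 81.35%. Recovery was not counted apart for probes that vary most between replicates. The median gene's SD within diets was 0.384 for heat shock and 0.302 for trophectoderm genes, against 0.154 over all genes. A shared 2-fold response in such variable genes stays open, as do smaller or rarer responses.

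Over the 8 sign changes of a comparison's 4 replicates no share under 0.05 can be had. For probes past the FDR the real count was 0 and the highest other 0, in FLX as in SUN, and any grouping is as large as a count of 0, so that the 8 of 8 say nothing. For probes at 1.5-fold, FLX had 35 with 114 as the highest other and 7 of 8 as large, and SUN had 86 with 647, which came from turning SUN replicate 3, and 4 of 8 as large. For lists, FLX had 1 with 3 as the highest other and SUN 0 with 8. For FLX vs SUN probes past the FDR, the real count was also 0, which all 35 splits reach by construction, so that the splits say nothing about chance. The highest other, 10, came from numbers 1 and 4 of both diets against the rest, again a structure by number.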
